A study of Homo sapiens with 9 samples.

How the data were processed

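Gene expression was measured on 9 arrays of total RNA from ARPE-19, an established human retinal pigment epithelial cell line. The labels name 3 arrays of vehicle control, 3 of cells given 100 µg/ml cigarette smoke condensate and 3 of cells given 250 µg/ml. Per the labels, confluent cells were moved to medium with albumin in place of serum, and the condensate was a DMSO stock of 40 mg/ml with 6% nicotine. The length of the treatment is not given in the sources used here. The labels number the arrays 1 to 3 in each group and do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

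The deposited values are log2 summaries, 1 per transcript-level probe set of an Affymetrix exon array, hybridised with whole-transcript sense-strand targets per the labels' protocols. The submitters' processing notes name RMA, Partek and genome build hg18. Versions, settings, the role of each tool and any filter on probe sets are not given in the sources used here. RMA subtracts background and normalizes arrays together, which compresses the fold changes of dim genes and hides any change in total RNA per cell. Array medians of the deposited log2 values lay between 4.42 and 4.59. Control replicate 1 had the lowest median and the lowest upper quartile (6.45). No detection calls were used here, so a low value does not tell whether a gene was expressed. The number of arrays and the spread between them both limit the precision.

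The value table held 17629 probe sets. The platform annotation gave 1 gene for 14378 of them, several genes for 2405 and no gene for 846. Symbols were updated by gene number through a RefSeq table of assembly GRCh38.p14, which lacked the gene number of 28 probe sets with 1 gene. Because that assembly is not the build of the arrays' annotation, no coordinates are given. Of 169 genes with more than 1 probe set, the probe set with the highest mean over the 9 arrays was used, which left 14207 genes. NQO1, SOD2 and HSP90B1 lay only on probe sets that name several genes and are not reported.

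Each comparison was fitted with limma 3.58.1 in R 4.3.3 on all 9 arrays with 1 mean per group, default empirical Bayes moderation and Benjamini-Hochberg adjustment over the 14207 genes, with a threshold of 0.05. Fold changes are on the log2 scale with the moderated standard error. Gene lists, 40 in all, were fixed before the data were examined, as were the limma and gene list tests of each comparison and most of the other settings tried. The 5 lists taken to answer the main question were NRF2 targets, ATF4 and CHOP branch genes, ER chaperones and folding enzymes, complex I subunits, and subunits of complexes II to V. Lists with at least 5 measured genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 39 lists of a comparison. Camera with an estimated correlation, camera on ranks and fry were run beside it. Genes that respond together make the preset correlation too low, so p-values from it can be far too small. The medians of the lists were also set against 10000 random lists matched on mean value. That test was chosen after the results had been seen, as were those of single low control arrays, of differences within array numbers and of gene families. For single control arrays the mean of a list on each array was fitted with 1 mean per group, which gave 95% intervals.

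The genes named were chosen by a rule. In each comparison it took the 5 largest rises and 5 largest falls among genes past the threshold whose arrays did not overlap between groups, and up to 4 members per described list among those past the threshold over all genes. It also took 20 genes whatever their values, of which CYP1A1, CYP1B1, HMOX1, GCLM, GCLC, TXNRD1, SLC7A11, HSPA5, DDIT3, ATF4, ATF3, XBP1, BCL2, BAX, VEGFA, CXCL8 and IL6 were measured alone. Other genes are named as chosen after their values were seen. The result of 1 gene that the rule takes is not reported here.

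Whether the array numbers pair the samples was checked from the correlation of deviations from the group means. Arrays of the same number at 100 and 250 µg/ml correlated at 0.44 to 0.68, and 6 of 6 samples correlated best with their own number. The numbers were therefore taken to pair both doses, a pairing that comes from the data and not from a statement in the labels. The main fits left this pairing out, and a replicate block was run as an alternative. Between either dose and the controls the lowest correlation was below 0, so no pairing was assumed there. Control replicate 1 did correlate at 0.26 and 0.23 with the arrays numbered 1 at 100 and 250 µg/ml. A pairing with the controls is therefore not excluded.

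The fits were tested on simulated data with 200 genes changed among 14207. In the simulation of 100 µg/ml against control, 80% of genes changed by 2-fold and 98% of those changed by 4-fold were called. For 250 µg/ml against control the shares were 72% and 94%, and for 250 against 100 µg/ml they were 66% and 96%. At 1.5-fold they were 18%, 12% and 22% in the same order, so most changes of that size would be missed. The simulations drew genes independently and gave 161, 144 and 146 calls in that order, of which 11, 4 and 4 were false. With fewer calls the Benjamini-Hochberg cut is stricter, so these shares are too high for comparisons with few calls. For the overlap of both doses, 100 simulations set unchanged groups against the same controls. Another 100, added after seeing the data, also gave dose arrays of the same number the mean observed correlation of 0.58. Alternatives covered the replicate block, each array left out in turn, dim genes, scaling, moderation, array weights, the arrays in the fit, the choice of probe set and the threshold.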

Results

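Transcript levels were compared in ARPE-19 cells, a human retinal pigment epithelial line, given vehicle, 100 µg/ml or 250 µg/ml cigarette smoke condensate, with 3 arrays per group. The series title asks about oxidative stress, mitochondrial dysfunction and the unfolded protein response. Arrays of a group correlated at 0.970 to 0.978 for the controls, 0.980 to 0.992 at 100 µg/ml and 0.982 to 0.992 at 250 µg/ml. The median SD per gene was 0.211 log2 units in the controls, 0.176 at 100 µg/ml and 0.155 at 250 µg/ml. On the first principal component, which held 38.3% of the variance, arrays 1 and 2 of both doses lay between -24.5 and -21.0. The arrays numbered 3 of the doses lay at 5.78 and 4.28, and the controls between 15.4 and 45.4. On the second component (19.4% of the variance) control replicate 1 lay at 33.1 and the other controls at 0.44 and -5.64.

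**Figure D1:**
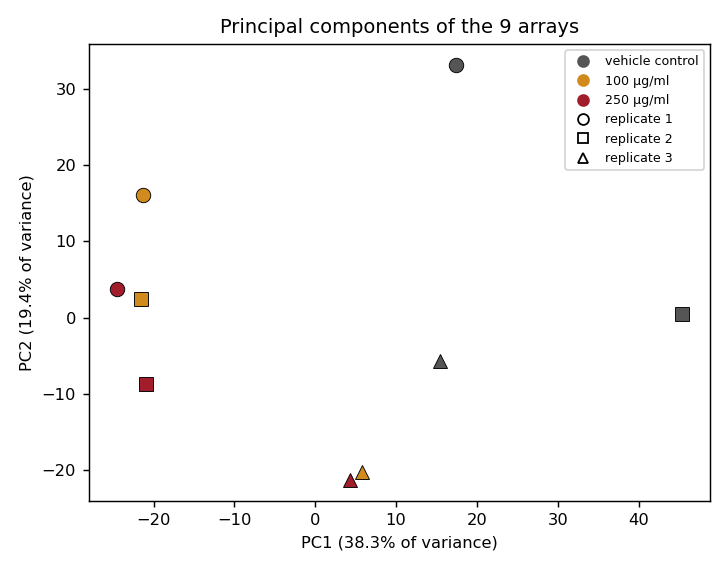
Scores of the 9 arrays on the first and second principal components (percent of variance on each axis label). Colour gives the group and shape the replicate number. The arrays numbered 3 of both doses, at 5.78 and 4.28 on the first component, lie apart from the other treated arrays.

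The first comparison asked which genes differ between cells given 100 µg/ml condensate and vehicle. The cystine transporter gene SLC7A11 rose 13.1-fold, by 3.71 ± 0.38 log2 units (SE, n = 3 per group, limma adjusted p = 0.0475). The cytochrome P450 gene CYP1A1, a target of the aryl hydrocarbon receptor, rose 6.64-fold, by 2.73 ± 0.19 (adjusted p = 0.0051). HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, rose 5.50-fold, by 2.46 ± 0.29 (adjusted p = 0.0485). The nicotinic receptor subunit gene CHRNA5 rose by 1.83 ± 0.21, the lipoprotein receptor gene LRP8 by 1.71 ± 0.20 and the ER chaperone gene HYOU1 by 1.55 ± 0.19, with adjusted p of 0.0485, 0.0485 and 0.0487. Lower than in the controls was the homeobox gene GSX2, which fell by 0.97 (SE 0.12, adjusted p = 0.0487). CYP1A1 had a control mean of 2.67, below the lower quartile of each array, so its fold rests on a level near the bottom of the scale.

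In all, 8 genes rose and 1 fell at 100 µg/ml among 14207 tested with limma, and the 3 treated arrays did not overlap the 3 controls in any of the 9. The other 2 were SLC1A4 and MLEC, named after their values were seen. At an unadjusted p under 0.05 there were 2081 genes where chance gives 710, of which 994 were higher and 1087 lower, and 1102 without CSC_100 replicate 2. Groups did not overlap in 18.3% of genes, against 10% by chance. The count and its split were unstable. Rises and falls were 4 and 4 without control replicate 2, 44 and 29 with array weights, and 22 and 25 without the arrays numbered 3 of both doses, a setting chosen after seeing the data. The count was 57 without control replicate 3, and 1, 1, 1 and 2 without control replicate 1, CSC_100 replicate 1, CSC_100 replicate 2 and CSC_100 replicate 3.

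NRF2 targets, genes of glutathione synthesis, NADPH supply and detoxification, rose as a group at 100 µg/ml, with a median change of 0.85 log2 units over 22 measured members (camera adjusted p = 1.1e-14, adjusted p = 0.0059 with an estimated correlation). Over all genes 2 members rose, SLC7A11 and HMOX1, and 14 rose when adjusted over the list alone. GCLM, the modifier subunit of glutamate-cysteine ligase, changed by 1.74 ± 0.31 and its catalytic partner GCLC by 0.85 ± 0.26, with adjusted p of 0.13 and 0.22 over all genes. TXNRD1, thioredoxin reductase 1, had a change of 0.85 ± 0.15 (adjusted p = 0.13). Among 9 AHR targets, CYP1A1 rose over all genes and 3 rose when adjusted over the list alone. CYP1B1 had a change of 2.07 ± 0.29 (adjusted p = 0.071 over all genes). The AHR list passed camera at 0.042 with a median of only 0.02, and had adjusted p = 0.41 with an estimated correlation. That call ended without control replicate 3 (0.093), CSC_100 replicate 1 (0.084) or CSC_100 replicate 3 (0.18), and the median ran from -0.026 to 0.18 with single arrays left out. The call also ended with array weights (0.35), on ranks (0.38) and without the arrays numbered 3 (0.22).

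All 3 lists of unfolded protein response genes passed camera in the upward direction at 100 µg/ml, and none of them passed with an estimated correlation. ER chaperones and folding enzymes rose by a median of 0.38 over 20 members (adjusted p = 5.7e-08, adjusted p = 0.29 with an estimated correlation). HYOU1 alone rose over all genes, and 7 members rose when adjusted over the list alone. HSPA5, the main ER chaperone BiP, had a change of 0.75 ± 0.33 (adjusted p = 0.34). The XBP1 branch and ER-associated degradation list passed at 2.7e-04 (median 0.16, and 0.28 without control replicate 2), with 0 members over all genes, 5 adjusted over the list alone and adjusted p = 0.29 with an estimated correlation. The ATF4 and CHOP branch passed at 0.036 with a median of 0.09 over 29 members, 0 past the threshold over all genes and 5 adjusted over the list alone, of which 4 were higher. It had adjusted p = 0.48 with an estimated correlation, and its call ended without control replicate 1 (0.12), control replicate 3 (0.082) or CSC_100 replicate 2 (0.12). The call also ended without dim genes (0.21), after quantile normalization (0.22) and on ranks (0.15), and its median ran from 0.028 to 0.16 with single arrays left out. DDIT3, which encodes CHOP, had a change of -1.06 ± 0.48 (adjusted p = 0.35), ATF4 one of -0.25 ± 0.24 (0.65), ATF3 one of -0.28 ± 0.26 (0.63) and XBP1 one of 0.28 ± 0.32 (0.72).

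Among the other lists, DNA replication genes had a median change of 0.99 and cell cycle and mitosis genes one of 0.85 at 100 µg/ml. In the mean of the treated arrays all 28 and 27 members lay above the control mean. Of these, 0 passed over all genes, and 17 and 13 rose when adjusted over the list alone. The mean of the DNA replication list, relative to its average over the arrays, was -0.087 in CSC_100 replicate 3. That lay below control replicate 3 (-0.052), so treated and control arrays overlapped. CSC_100 replicates 1 and 2 lay at 0.69 and 0.89, and control replicates 1 and 2 at -0.32 and -1.13. For cell cycle genes the lowest treated array (0.315) lay above the highest control (-0.079). Both lists passed camera (3.8e-16 and 1.8e-17), with adjusted p = 0.32 and 0.26 with an estimated correlation. The proteasome list rose by a median of 0.40 (2.2e-07, adjusted p = 0.41 with an estimated correlation), which was 0.087 without control replicate 1 (0.014, adjusted p = 0.43 with an estimated correlation). The cytosolic heat shock list (0.24, 0.0047) and the citrate cycle list (0.25, 0.0090) also passed, each with adjusted p = 0.26 with an estimated correlation, and the second call ended without CSC_100 replicate 3 (0.059). Without dim genes both calls ended (0.077 and 0.14), as they did after quantile normalization (0.063 and 0.17), and the citrate cycle call ended without the arrays numbered 3 (0.062). The heat shock median was 0.39 without control replicate 2 and 0.14 without CSC_100 replicate 2. Retinal pigment epithelium identity genes fell by a median of 0.17 (camera adjusted p = 0.020) and angiogenic growth factors by 0.21 (0.0094), both with adjusted p = 0.26 with an estimated correlation. The identity call ended without control replicate 3 (0.099). VEGFA had a change of -1.11 ± 0.26 (adjusted p = 0.20).

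**Figure D2:**
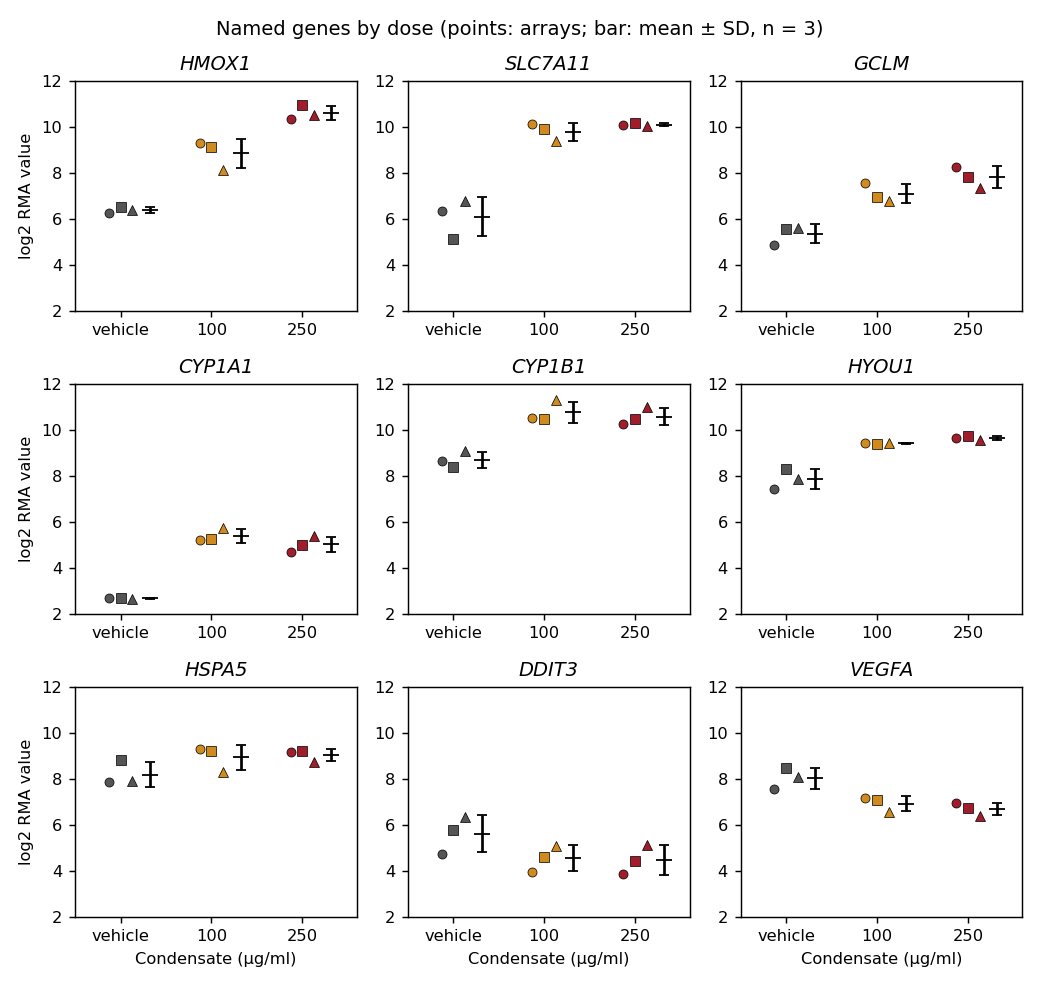
Deposited log2 RMA values of 9 genes against condensate dose. Points are arrays, shapes the replicate number, and bars the mean and SD of 3 arrays. HMOX1 has group means of 6.39, 8.85 and 10.61 in vehicle, 100 and 250 µg/ml, while the arrays of DDIT3 overlap between the groups.

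The comparison of 250 µg/ml with vehicle gave the larger number of genes past the threshold. HMOX1 rose 18.7-fold, by 4.23 ± 0.29 log2 units (n = 3 per group, limma adjusted p = 0.0042), and SLC7A11 16.2-fold, by 4.02 ± 0.38 (0.0089). GCLM rose 5.48-fold, by 2.45 ± 0.31 (0.020), CYP1A1 5.10-fold, by 2.35 ± 0.19 (0.0081), and SEL1L3 4.97-fold, by 2.31 ± 0.36 (0.045). The interleukin 7 receptor gene IL7R fell by 2.74 (SE 0.28, adjusted p = 0.0089), which is 6.66-fold lower. NEBL, encoding the actin-binding protein nebulette, fell by 2.49 (SE 0.38), the transglutaminase gene TGM1 by 2.43 (SE 0.39) and the organic anion transporter gene SLCO1A2 by 1.63 (SE 0.16). Their adjusted p were 0.043, 0.047 and 0.0089.

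At 250 µg/ml 55 genes rose and 23 fell, of which 36 and 15 changed at least 2-fold, and the arrays of both groups did not overlap in any of the 78. At an unadjusted p under 0.05 there were 2364 genes where chance gives 710, and 1573 and 1449 without CSC_250 replicates 1 and 2. Groups did not overlap in 22.9% of genes. The split between rises and falls moved with the scaling of the arrays. Centring each array on its median gave 93 rises and 71 falls, and quantile normalization 76 and 72. The count was 296 without control replicate 3, 19 without CSC_250 replicate 1 and 4 without CSC_250 replicate 2. It was 1 with only the 6 arrays of the comparison and 3 with unmoderated variance.

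The NRF2 targets had the largest median change of the lists at 250 µg/ml, 1.35 log2 units over 22 members (camera adjusted p = 2.9e-19, adjusted p = 0.0025 with an estimated correlation). Over all genes 6 members rose and 17 when adjusted over the list alone. Besides HMOX1, SLC7A11 and GCLM these 6 held PIR, an iron-binding nuclear protein gene that rose by 2.03 ± 0.18, and, named after their values were seen, ME1 and SRXN1. GCLC had a change of 1.49 ± 0.26 (adjusted p = 0.052) and TXNRD1 one of 0.75 ± 0.15 (0.069). Among AHR targets CYP1B1 rose by 1.88 ± 0.29 (0.043) beside CYP1A1. The AHR list did not pass (0.13), and its median of -0.06 had the opposite sign to its mean of 0.46. It passed upward in 1 of 18 alternatives, without dim genes (0.0098). Of the glutathione S-transferases, whose list did not pass (0.13), GSTA4 rose by 1.46 ± 0.17 (0.015).

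ER chaperones and folding enzymes rose by a median of 0.46 at 250 µg/ml (camera adjusted p = 1.9e-07, adjusted p = 0.28 with an estimated correlation). Over all genes 3 of 20 rose and 7 when adjusted over the list alone. The 3 were HYOU1 (1.77 ± 0.19, adjusted p = 0.011) and the BiP co-chaperone genes DNAJC3 (1.06 ± 0.18, 0.050) and DNAJB11 (0.99 ± 0.13, 0.024). HSPA5 itself had a change of 0.86 ± 0.33 (0.25). In the XBP1 branch and ER-associated degradation list, SSR3 of the translocon-associated complex rose by 1.49 ± 0.24 (0.049), with 1 of 27 members over all genes and 7 adjusted over the list alone. That list passed at 1.6e-04, with adjusted p = 0.28 with an estimated correlation. Its median of 0.26 was 0.031 without control replicate 1 and 0.16 without CSC_250 replicate 3.

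The ATF4 and CHOP branch did not pass at 250 µg/ml (adjusted p = 0.23, median 0.02). Its 2 members past the threshold over all genes went opposite ways, and 4 passed when adjusted over the list alone, of which 3 were higher. SLC3A2, the heavy chain that partners the SLC7A11 transporter, rose by 1.01 ± 0.13 (0.020), and the thioredoxin-binding protein gene TXNIP fell by 1.57 (SE 0.17, 0.011). DDIT3 had a change of -1.15 ± 0.48 (0.28), ATF4 one of -0.10 ± 0.24 (0.85), ATF3 one of -0.56 ± 0.26 (0.32) and XBP1 one of 0.26 ± 0.32 (0.71). The apoptosis regulators BCL2 (-0.37 ± 0.18, 0.36) and BAX (-0.40 ± 0.31, 0.55) did not pass, as they did not at 100 µg/ml (-0.41 ± 0.18, 0.36, and -0.51 ± 0.31, 0.48).

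Respiratory chain genes were not called at either dose with all arrays. The 27 measured subunits of complex I had medians of 0.06 at 100 µg/ml and 0.08 at 250 µg/ml (camera adjusted p = 0.38 and 0.39). The 29 subunits of complexes II to V had medians of -0.14 and -0.11 (0.62 and 0.63), and 0 members of either list passed, over all genes or adjusted over the list alone. Below the control mean lay 20 of these 29 subunits at 100 µg/ml and 19 at 250 µg/ml. Among the matched random lists the medians of complexes II to V lay at percentiles 0.95 and 1.87. Those of complex I lay at 53.5 and 49.8. Genes in random lists were drawn independently, so a list whose genes vary together reaches low percentiles more easily. Single controls set the sign of these medians. Those of complex I were -0.12 and -0.18 without control replicate 1, 0.12 and 0.23 without control replicate 2, and 0.076 and 0.17 without control replicate 3, and none of these passed. Those of complexes II to V were 0.019 and 0.039 without control replicate 2, and 0.064 and 0.052 without control replicate 3. Without control replicate 1, which was low in both lists, complexes II to V were called lower, with medians of -0.33 (0.011) and -0.41 (0.0055), but had adjusted p = 0.57 and 0.49 with an estimated correlation. Of the genes in mitochondrial DNA only ND5 and ND6 were measured alone, too few for a test. The citrate cycle list passed at 250 µg/ml (0.034, median 0.20, adjusted p = 0.28 with an estimated correlation), with a 2.82-fold rise of IDH1 (limma adjusted p = 0.025) and 2 members rising when adjusted over the list alone. IDH1 encodes the cytosolic and peroxisomal isocitrate dehydrogenase that makes NADPH. The citrate cycle call ended without control replicate 1 (0.087) or CSC_250 replicate 3 (0.058), and its median was 0.12 without CSC_250 replicate 1. The call also ended without dim genes (0.35), after quantile normalization (0.24), with the replicate block (0.078), with only the 6 arrays of the comparison (0.066), on ranks (0.093) and without the arrays numbered 3 (0.097).

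Other lists that rose at 250 µg/ml were the proteasome (median 0.53, 4.8e-08), cytosolic heat shock (0.33, 4.9e-04), fatty acid synthesis and lipid droplets (0.24, 0.0056), cell cycle and mitosis (0.50, 2.9e-07) and DNA replication (0.47, 9.7e-05). Their adjusted p with an estimated correlation were 0.31, 0.28, 0.28, 0.36 and 0.57. List means, relative to their average over the arrays, overlapped between groups for DNA replication and cell cycle. CSC_250 replicate 3 lay below control replicate 3 in both, at -0.197 against -0.052 and at -0.0835 against -0.0786. CSC_250 replicates 1 and 2 lay above every control in both. PSMA4 of the proteasome rose by 0.81 ± 0.14 (0.049), as 1 of 26 members over all genes and 5 adjusted over the list alone. ELOVL6, a fatty acid elongase gene, rose by 2.06 ± 0.28 (0.029), as 1 of 16 members over all genes and 4 adjusted over the list alone. The fatty acid call ended without control replicate 3 (0.13), without dim genes (0.078) and without the arrays numbered 3 (0.0505), and the DNA replication call without control replicate 2 (0.096). Without control replicate 1 the medians were 0.24 for the proteasome and 0.41 for fatty acid synthesis. Without control replicate 2 they were 0.26 for cell cycle, 0.14 for DNA replication and 0.54 for heat shock. Without control replicate 3 they were 0.74 for DNA replication and 0.077 for fatty acid synthesis, which had 0.087 without CSC_250 replicate 3.

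Lists that fell at 250 µg/ml were glycolysis and hypoxia (median -0.45, 4.1e-04), angiogenic growth factors (-0.26, 0.0019), epithelial-mesenchymal genes and matrix (-0.20, 0.0085), matrix metalloproteinases and inhibitors (-0.25, 0.0097), complement and its regulators (-0.30, 0.029) and retinal pigment epithelium identity (-0.23, 0.029). With an estimated correlation their adjusted p were 0.54, 0.28, 0.37, 0.37, 0.28 and 0.28. The hypoxia-responsive gene NDRG1 fell by 1.35 (SE 0.16, 0.013). VEGFA, the vascular endothelial growth factor gene in the first and second of these lists, had a change of -1.34 ± 0.26 (0.063). Markers of fibroblasts, a list fixed for another cell type, fell by a median of 0.22 (0.029, adjusted p = 0.31 with an estimated correlation), and share COL3A1 and COL6A3 with the matrix list. CXCL8 (-0.02 ± 0.16) and IL6 (-0.24 ± 0.14) did not pass (0.97 and 0.41), nor at 100 µg/ml (0.09 ± 0.16, 0.84, and -0.09 ± 0.14, 0.78). Both genes lay between 2.54 and 3.22 on every array, near the arrays' lower quartiles of 2.89 to 3.10, so a change may not be visible. Calls ended for complement without control replicate 1 (0.056), control replicate 3 (0.11) or CSC_250 replicate 1 (0.086). Others ended for the identity list without control replicate 3 (0.11) or CSC_250 replicate 1 (0.054), for matrix genes and fibroblast markers without control replicate 1 (0.072 and 0.097) and for glycolysis without CSC_250 replicate 3 (0.053). After quantile normalization calls ended for metalloproteinases (0.056), identity (0.053) and fibroblast markers (0.0995), and without the arrays numbered 3 for matrix genes (0.051). Medians were -0.26 for glycolysis without CSC_250 replicate 3, -0.19 for complement without control replicate 3 or CSC_250 replicate 1, and -0.10 for identity without control replicate 3. They were -0.086 for matrix genes without control replicate 1 and -0.086 for metalloproteinases without control replicate 2.

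**Figure D3:**
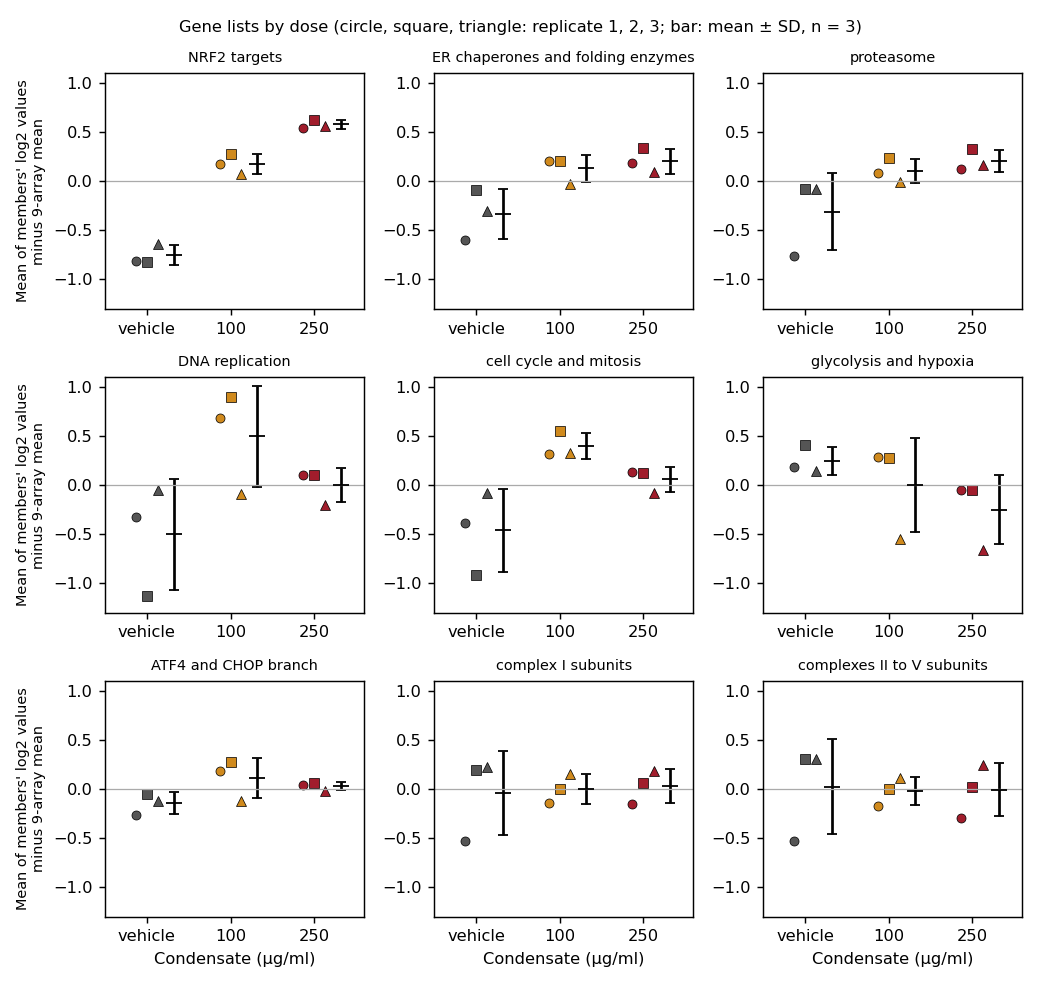
Mean log2 value of a list's members on each array, minus the mean over the 9 arrays, against condensate dose. Points are arrays and bars the mean and SD of 3 arrays. All treated arrays lie above all controls for NRF2 targets, while treated and control arrays overlap for both respiratory chain lists.

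The third comparison set 250 against 100 µg/ml, to test the difference between the doses itself. HMOX1 was 1.77 ± 0.29 log2 units higher at 250 µg/ml (3.41-fold, n = 3 per group) with an unadjusted p of 2.5e-04 and a limma adjusted p of 1.00, so the difference did not pass over all genes. CYP1A1 had a difference of -0.38 ± 0.19, CYP1B1 one of -0.19 ± 0.29, SLC7A11 one of 0.30 ± 0.38, GCLM one of 0.71 ± 0.31 and HSPA5 one of 0.10 ± 0.33, each with an adjusted p of 1.00. With limma 0 of 14207 genes passed, 262 had an unadjusted p under 0.05 where chance gives 710, and groups did not overlap in 6.17% of genes. That fit left out the pairing of the dose arrays, which can hold such counts below chance. The low count therefore does not show that the doses agree. The number with an unadjusted p under 0.05 was 132 without CSC_100 replicate 2, 739 without CSC_100 replicate 3 and 2276 with array weights. With the arrays paired by number 0 genes passed, and that number was 467 with the block on all 9 arrays and 1593 with the block on the 6 dose arrays alone, a setting chosen after seeing the data.

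NRF2 targets rose further from 100 to 250 µg/ml, by a median of 0.29 (camera adjusted p = 1.7e-10, adjusted p = 0.015 with an estimated correlation), with 0 members over all genes and 3 adjusted over the list alone. Of the lists tested, 6 more differed between the doses, each with adjusted p = 0.64 with an estimated correlation and 0 members past the threshold over all genes or adjusted over the list alone. Metallothioneins were higher by a median of 0.39 (0.0068). DNA replication was lower by a median of -0.51 (3.5e-13), cell cycle and mitosis by -0.37 (2.2e-09), glycolysis and hypoxia by -0.23 (1.2e-05), matrix genes by -0.12 (8.0e-04) and p53 targets by -0.10 (0.0044). With array weights the metallothionein and p53 calls ended (0.069 each), as they did without the arrays numbered 3 (0.30 and 0.058). The metallothionein call ended with the block on the 6 dose arrays (0.071), without CSC_100 replicate 3 (0.097) or CSC_250 replicate 3 (0.17) and the glycolysis call without CSC_250 replicate 3 (0.20). The p53 call ended without CSC_100 replicate 3 (0.39), CSC_250 replicate 1 (0.11) or CSC_250 replicate 2 (0.085). The ATF4 and CHOP branch did not pass between the doses (camera adjusted p = 0.13), but was called lower at 250 µg/ml in 3 of 19 alternatives. Those were array weights, without the arrays numbered 3 and without CSC_100 replicate 3 (lowest adjusted p 0.0060). Single arrays left out moved the medians to between -0.80 and -0.29 for DNA replication (CSC_100 replicates 3 and 2) and -0.25 for cell cycle (CSC_100 replicate 2). For matrix genes they were -0.19 and -0.076 (CSC_250 replicate 1 and CSC_100 replicate 1), and for metallothioneins 0.21 and 0.047 (CSC_250 replicates 2 and 3). Glycolysis had -0.45, -0.11, -0.10 and -0.083 (CSC_100 replicates 3, 1 and 2 and CSC_250 replicate 3), and p53 targets -0.24, -0.21, -0.045 and -0.042 (CSC_250 replicate 3, CSC_100 replicates 2 and 3 and CSC_250 replicate 2).

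The responses to both doses were then set side by side. All 9 genes called at 100 µg/ml were called in the same direction at 250 µg/ml, where lists drawn independently would share 0.031 rises and 0.0016 falls. Those figures leave out the shared controls and the pairing of the dose arrays by number. Simulated unchanged groups that share these controls had a mean of 0 genes called at both doses, and of 0.04 with the dose arrays also paired at their observed mean correlation of 0.58, a simulation added after seeing the data. Unchanged groups give almost no calls after adjustment in either comparison, so these counts were near 0 in advance and do not test the overlap. Across genes, which are not independent replicates, the changes correlated at 0.87, against 0.50 for the unpaired simulation and 0.79 for the paired one. The covariance was 0.119 against simulated 0.0245 and 0.0383, differences of 0.0947 and 0.0809. Signs matched in 83.2% of genes against 66.6% and 78.9%. The simulations drew genes independently, while on real arrays many genes deviate together. Unchanged real groups could therefore lie further from these simulated means than the simulations show. The 3 controls are too few to be split into groups of 2, so part of the excess may come from the shared controls and the pairing.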

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

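The tests of single low control arrays and their criteria, and the tests of differences within array numbers and of random lists matched on mean value were chosen after the results had been seen, and the set without the arrays numbered 3 was added after seeing the data. Other splits of the samples were planned. For single low control arrays the criterion was changed repeatedly after results were seen. The intervals given below were chosen with their values seen.

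A test of the difference between the doses singled out 7 lists, with camera adjusted p of 1.75e-10 for NRF2 targets, 3.46e-13 for DNA replication, 2.19e-09 for cell cycle and mitosis, 1.16e-05 for glycolysis and hypoxia, 8.01e-04 for matrix genes, 0.00441 for p53 targets and 0.00684 for metallothioneins. With an estimated correlation NRF2 targets alone stayed past the threshold. Among 3251 probe sets that name several genes or none, which the main comparisons left out, 5 were higher and 5 lower at 250 µg/ml than in the controls. These calls come from the fit over all probe sets.

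The real grouping gave 9 genes at 100 µg/ml and 78 at 250 µg/ml, and the highest of the other splits gave 0 in each case, so 1 of the 10 splits gave as many. Between the doses the real grouping gave 0 genes, and all 10 splits gave as many. With 10 splits no share under 0.05 can be reached.

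DNA replication and cell cycle genes were higher than control at 100 µg/ml and lower at 250 than at 100 µg/ml. The higher level of DNA replication genes was not seen in every treated array. The mean of that list, relative to its average over the arrays, was -0.087 in CSC_100 replicate 3 and -0.052 in control replicate 3. A rise shared by all genes of similar brightness is argued against, since both medians lay at percentile 100 of the matched random lists. Control replicate 2 was the lowest array in both lists, and without it both kept their camera calls at 100 µg/ml (larger adjusted p 5.16e-11), though with an estimated correlation neither passed with all arrays (0.32 and 0.26) or without it (0.39 and 0.20). Over the remaining arrays the mean change of cell cycle genes was 0.63 (95% interval 0.28 to 0.98). An interval chosen with its values seen is weak evidence against that array as the whole cause. For DNA replication genes the mean change was 0.69 (-0.15 to 1.52), so there the array stays open. All 6 within-number differences between the doses, 3 per list, were below 0, which with 3 pairs cannot reach a two-sided sign test p below 0.25, so an effect of dose on proliferation and culture differences in growth state both remain possible.

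ER chaperones were higher than control at both doses by camera at its preset correlation. At 250 µg/ml the median lay at percentile 100 of the matched random lists, which argues against a rise of all genes of that brightness. Control replicate 1 was the lowest array, as it was in the proteasome, XBP1 branch, complex I and complexes II to V lists. Its deviation was thus not particular to ER chaperones. Without it the camera adjusted p at 250 µg/ml was 2.37e-05, though with an estimated correlation the list passed neither with all arrays (0.28) nor without it (0.33). The mean change over the remaining arrays was then 0.33 (95% interval 0.013 to 0.64) at 100 µg/ml and 0.40 (0.085 to 0.71) at 250 µg/ml. Both lower bounds were positive, though narrowly at 100 µg/ml. Because the intervals were chosen with their values seen, they are weak evidence against that array as the whole cause. An effect of the condensate and differences between cultures unrelated to it both remain possible.

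The count of 9 genes at 100 µg/ml may reflect the spread that the arrays numbered 3 of both doses add. Without both, 47 genes were called, but without CSC_100 replicate 3 alone there were 2, and without control replicate 3 there were 57. These counts go both ways, so this explanation stays open, beside a smaller effect of the lower dose.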

How the results depend on the processing

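The settings without the arrays numbered 3 and the replicate block on 6 arrays, and the paired simulation, were added after seeing the data; the others were planned. Where a value moved, the cause was not tested. For 100 µg/ml, where 9 genes were called, counts were 3 with the replicate block, 5 after quantile normalization, 73 with array weights, 1 with only the 6 arrays of the comparison, 0 with unmoderated variance, 1 over all probe sets, 1 at an adjusted p under 0.01, 47 without the arrays numbered 3, and 1 to 57 with single arrays left out. For 250 µg/ml, where 78 were called, the same settings gave 122, 148, 234, 1, 3, 71, 13, 167 and 4 to 296, and counts were 157 without dim genes, 164 after median centring, 170 with trend and robust moderation and 51 at 2-fold or more. Between the doses 0 genes were called in each setting run, the replicate block included. Between a dose and the controls no pairing by number was assumed (2 of 6 samples correlated best with their own). There the replicate block ended 1 list call, citrate cycle at 250 µg/ml (0.078). Between the doses it changed no call with all arrays. On 6 arrays it ended the metallothionein call (0.071) and added one for matrix metalloproteinases and inhibitors, lower at 250 µg/ml (0.040). ATF4 and CHOP branch genes at 100 µg/ml (0.036) had adjusted p of 0.212 without dim genes, 0.218 after quantile normalization, 0.480 with an estimated correlation, 0.247 with fry, 0.149 on ranks and 0.00466 to 0.122 with single arrays left out. ER chaperones had 0.288 and 0.278 with an estimated correlation and 0.0827 and 0.0504 with fry at 100 and 250 µg/ml. Fry also missed, at 100 µg/ml, AHR targets, the XBP1 branch, heat shock, citrate cycle, proteasome, cell cycle and DNA replication (0.0519 to 0.167). At 250 µg/ml it missed the XBP1 branch, citrate cycle, proteasome, cell cycle, DNA replication, complement, matrix genes, metalloproteinases, fatty acid synthesis and glycolysis (0.0504 to 0.401), and between the doses each called list except NRF2 targets (0.881 to 0.955). Complexes II to V ranged from 0.0112 to 0.721 and from 0.00550 to 0.795 with single arrays left out. Matched random lists, chosen after the results had been seen, were set beside the list calls. At 100 µg/ml AHR targets, the ATF4 and CHOP branch and the XBP1 branch lay at percentiles 74.4, 80.1 and 91.7. Heat shock and citrate cycle lay at 95.4 and 93.3 there, and citrate cycle at 83.0 at 250 µg/ml. These medians were within the central 95% of the random lists, while those of the other called lists were outside. NRF2 targets kept their direction and side of the threshold in 18 of 18 alternatives at each dose and 19 of 19 between doses. At 100 and 250 µg/ml fry kept angiogenic growth factors (0.029 and 0.016) and retinal pigment epithelium identity (0.035 and 0.034). It also kept heat shock and fibroblast markers at 250 µg/ml (0.034 each). Angiogenic growth factors passed in 17 of 18 alternatives at each dose and missed the threshold with an estimated correlation. HMOX1 at 250 µg/ml and CYP1A1 at 100 µg/ml stayed past the threshold in 16 of 17 alternatives, stricter thresholds not counted, and missed it with unmoderated variance (0.0539 and 0.0824). All calls of genes taken by the rule ended with unmoderated variance, 7 at 100 µg/ml and 23 at 250 µg/ml. Most were less stable than HMOX1 and CYP1A1 in other settings too. At 100 µg/ml 6 ended over all probe sets, with only the 6 arrays, and with the replicate block. As many ended without control replicate 1, CSC_100 replicate 1 or CSC_100 replicate 2. At 250 µg/ml 22 ended with only the 6 arrays, 19 without CSC_250 replicate 2 and 14 without CSC_250 replicate 1. The correlation between the doses was 0.864 to 0.904 with single controls left out. No detection calls were used, so signal over background is unknown.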

Other observations

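The family test below and the genes named here were chosen after the results had been seen.

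Among the 55 genes that rose at 250 µg/ml were 8 of the solute carrier (SLC) family, the membrane transporters. They were SLC7A11 and SLC3A2, which together form the cystine and glutamate exchanger, the neutral amino acid transporter genes SLC1A4 and SLC43A2, the taurine transporter gene SLC6A6, the nucleotide sugar transporter genes SLC35B4 and SLC35D1, and the fatty acid transport gene SLC27A4. SLC6A6 rose by 1.78 and SLC35B4 by 1.48 log2 units. Genes whose symbol is SLC followed by a digit were 14.5% of the rises and 2.13% of the genes tested, with 0 among the falls. The organic anion transporter gene SLCO1A2, a solute carrier outside that symbol rule, fell by 1.63. Over 64 symbol families with at least 20 tested genes, SLC alone passed a one-sided Fisher exact test (p = 1.94e-05, adjusted p = 0.00124), in which genes are treated as independent. All 302 SLC genes had a median change of -0.03 at 250 µg/ml and did not pass limma's camera (adjusted p = 0.47 over 4 tests, direction up against the sign of the median). The other 294, left after the called genes were taken out, had a median of -0.04 (camera adjusted p = 0.57, direction also up). Because that set was picked by the same values, it is no separate test. The hypothesis that condensate may raise transporter genes rests on the 8 that were called, some of which are known NRF2 or ATF4 targets.

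Other lists did not pass in any comparison. They include pro-apoptotic genes, with medians of -0.11 at 100 µg/ml and -0.08 at 250 µg/ml (camera adjusted p = 0.83 and 0.88), inflammatory cytokines and NF-kB targets (-0.13 and -0.17, 0.23 and 0.13), interferon response genes (-0.12 and -0.09, 0.55 and 0.39) and antioxidant enzymes outside the NRF2 list (0.04 and 0.10, 0.38 and 0.63). Photoreceptor, Mueller glia, endothelial and leukocyte markers, fixed for other cell types, had adjusted p of 0.14, 0.39, 0.39 and 0.14 at 250 µg/ml. In lists that were not called, the sign of the median or mean differed from camera's direction in 5 of 27 at 100 µg/ml, 3 of 23 at 250 µg/ml and 8 of 32 between the doses.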
